A study of Lactococcus cremoris subsp. cremoris UC509.9 with 30 samples.

How the data were processed

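RNA of UC509.9 was hybridised to 30 custom Agilent arrays with a green (Cy3) and a red (Cy5) channel. Per the labels, cultures for infection were grown in M17 with 0.5% glucose at 30 °C to an OD600 of 0.13, received CaCl2 to 10 mM and were divided into equal parts, one given phage at a multiplicity of infection of 5 and the other the same buffer alone. On each of the 28 infection arrays green is infected and red is mock RNA of the same culture, and on the 2 lysogen arrays green is the lysogen and red the cured strain. For the lysogen arrays the labels give M17 with glucose but no OD600, temperature or CaCl2. No dye swap exists. A dye effect specific to a locus therefore adds to every ratio. Among the main comparisons of host loci it cancels only in the difference between phages. If constant, it also cancels in the alternative that subtracts the 0 min arrays. Actinomycin D was used in the labelling, per the labels, to limit synthesis of a second cDNA strand.

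The authors scanned the arrays with Agilent Feature Extraction 9.5. Per the file headers, the deposited scanner tables hold mean pixel intensity and local background intensity for each spot and channel, a processed intensity after background subtraction and dye normalization, a log10 ratio of red over green, and flags. The deposited series table holds a normalised log10 ratio, whose sign and scale were checked against the scanner tables. Each array holds 45171 spots: 15532 for host loci, 19085 tiles of Tuc2009, 8337 tiles of c2, 800 further probes that were not used and 1417 controls. The arrays lie on 9 slides scanned on 6 days, and each slide holds arrays of at most 1 culture, apart from the slide shared by the lysogen and late c2 arrays of replicate 2.

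Mean intensity was corrected with local background by normexp (saddle point, offset 50) in limma 3.58.1 under R 4.3.3. Spots flagged as outliers were left out. The log2 ratio of green over red was normalised on each array by a loess (span 0.3, 4 iterations) fitted to host probes with phage tiles at weight 0, since phage RNA took most of the late signal. The value of a locus is the mean over its probes (median 7 probes). A locus was tested if a probe was well above background in at least 1 channel on at least 2 arrays, which left 2580 of 2581. Host probes are of sense sequence: 99.2% have an open frame as printed and 76.3% on the other strand.

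limma was fitted with 1 coefficient for each of the 15 groups and no other term, which leaves 15 residual degrees of freedom shared by groups of 2 arrays. Windows are means of coefficients, tested against 0, and the contrast of late c2 minus late Tuc2009 tests the difference itself. All tests are two-sided, with Benjamini-Hochberg adjustment over host loci at 0.05. Arrays of a culture taken at successive times are not independent, so p-values without a block treat them as more replicates than there are cultures, 2 per phage. Fits with the culture as a random or fixed block were run for that reason, and slide and scan day were also tried as random blocks. The median ratio of host probes lies near 0 on each array by construction.

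Groups, tests, alternatives and the rule for naming loci were fixed before the data were examined. The rule took the 12 highest and 12 lowest loci of each late window, and the 6 highest and 6 lowest of the difference and of the lysogen, among those past the threshold with the same sign in every replicate. The files pair no locus tag with a symbol and the table of names matched 0 of the tags, so at most 2 tags per direction are printed. For the same reason the functional gene lists that had been fixed had no members and could not be tested. Classes read from tags and probe sequences took their place after the files were seen: tRNA, rRNA, each plasmid (pCIS tags), loci sharing a probe sequence with others, loci with a window of 19 residues of mean hydropathy of at least 1.6 on at least 2 probes, and motifs of ATPases, transporters and anchored proteins. Classes of at least 3 loci were tested with camera at a preset correlation of 0.01, and no call held with an estimated correlation.

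Phage sequences were rebuilt from the tiles (38606 and 22171 positions, numbered as in the probe names), and reading frames were predicted with Prodigal 2.6.3, which gave 54 frames for Tuc2009 and 37 for c2. Host probes were matched to them with BLAST 2.17.0 (at least 40 bp), and 26 loci had a match. Shares of signal are sums of background-subtracted mean intensity over all spots that are not controls. For changes over time, the infected level of a tile relative to the mean signal of its array was summarised as the median over bins of 1000 bp and tested with limma between windows within a phage, so a bin can fall because others rise. The time from which a bin was present is the earliest from which the log2 ratio of both replicates stayed more than 1 above the highest array of the other phage. Lysogen bins are values without a test.

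Alternatives were Agilent's processed signals, the deposited series values, median centring, a loess on all probes, no filter, detection on all 30 arrays, the median over probes, at least 2-fold, array quality weights, fits on the arrays of a single phage, subtraction of the 0 min arrays, 500 bp bins, the mean over tiles and unsaturated tiles, the blocks above, and leaving out each replicate. Further alternatives were chosen after seeing the data: detection in both channels, leaving out the lysogen and 0 min arrays, leaving out loci that match the phages, the ratio in place of the level for bins, a block for bins, and leaving out each replicate for the lysogen bins. With 1 replicate of a phage left, bins were fitted with the windows as groups, so that the times within a window stand in for replicates.

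The steps were tested on simulated data with the spread of the residuals. Of 200 loci changed by 1 (log2), 93.5% were recovered in the late Tuc2009 window, 88.5% in the late c2 window, 76.0% in the difference and 79.0% in the lysogen, among 2580 loci. At 0.5 (log2) the shares were 50.5%, 49.5%, 14.5% and 17.5%. All 15 of 78 bins changed by 3 (log2) were recovered for Tuc2009 from middle to late.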

Results

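The series followed *Lactococcus* UC509.9, a dairy starter strain, through lytic infection by Tuc2009 and by c2. Tuc2009 is a temperate phage, able to lyse its host or to persist in its chromosome, and c2 is a lytic phage. Of the 30 arrays, 28 carried labelled RNA of infected cells in the green channel and of mock-treated cells from the same culture in the red channel. Tuc2009 was sampled at 0, 2, 5, 10, 15, 25, 35 and 45 min, of which the protocol in the labels does not describe 0 min, and c2 at 2, 5, 10, 15, 25 and 35 min. A further pair of arrays compared cells carrying Tuc2009 as a prophage, the lysogen, with the cured strain. Each of the 15 groups held 2 arrays, and this number limits the precision of every value. The arrays carried probes for 2581 host loci and tiles along both strands of both phage genomes, with a median step of 4 bp for Tuc2009 and 5 bp for c2. The question stated in the title of the series was whether the phages trigger different host responses. Windows were called early (2 and 5 min), middle (10 and 15 min) and late (25 and 35 min).

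Host loci gave a signal well above background for 48.5% to 100% of loci in the infected channel and for 85.5% to 99.8% in the mock channel. The host share of the infected signal was 72.4% ± 6.0 (SD, n = 2) at 2 min of c2 infection and 6.6% ± 2.1 at 35 min. At 45 min of Tuc2009 infection it was 6.5% ± 0.8 (SD, n = 2). In the mock channel the mean host share lay between 83.4% and 91.6% at all times. Host ratios are therefore relative to the other host transcripts on the same array and do not give absolute amounts.

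Tuc2009 tiles carried 34.6% ± 11.9 (SD, n = 2) of the infected signal at 2 min, 67.6% ± 11.9 at 25 min and 92.8% ± 0.8 at 45 min. In mock cells of the same series they carried 4.40% to 14.6%, and on the c2 arrays 1.36% to 13.2% of the infected signal. At 0 min the share was 41.5% ± 10.0, with 65.9% ± 3.1 of it on forward tiles. In replicate 2 at 0 min the median forward ratio was 1.26 (log2) for Tuc2009 tiles and 1.04 for c2 tiles. Tuc2009 tiles thus stood little above those of the absent phage there, while in replicate 1 the medians were 3.35 and -0.79. From 2 min on, forward tiles carried 86.3% ± 0.6 or more of the phage signal. The c2 tiles carried 20.1% ± 5.0 (SD, n = 2) of the infected signal at 2 min, 29.1% ± 1.2 at 5 min and 81.5% ± 4.0 at 10 min, against 0.74% to 3.14% in mock cells. On the arrays of Tuc2009 infection they carried 0.42% to 15.5% of the infected signal (median 1.63%). At 2 min, forward tiles held 30.2% ± 9.7 of the c2 signal, and at 35 min they held 93.2% ± 4.5.

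**Figure D1:**
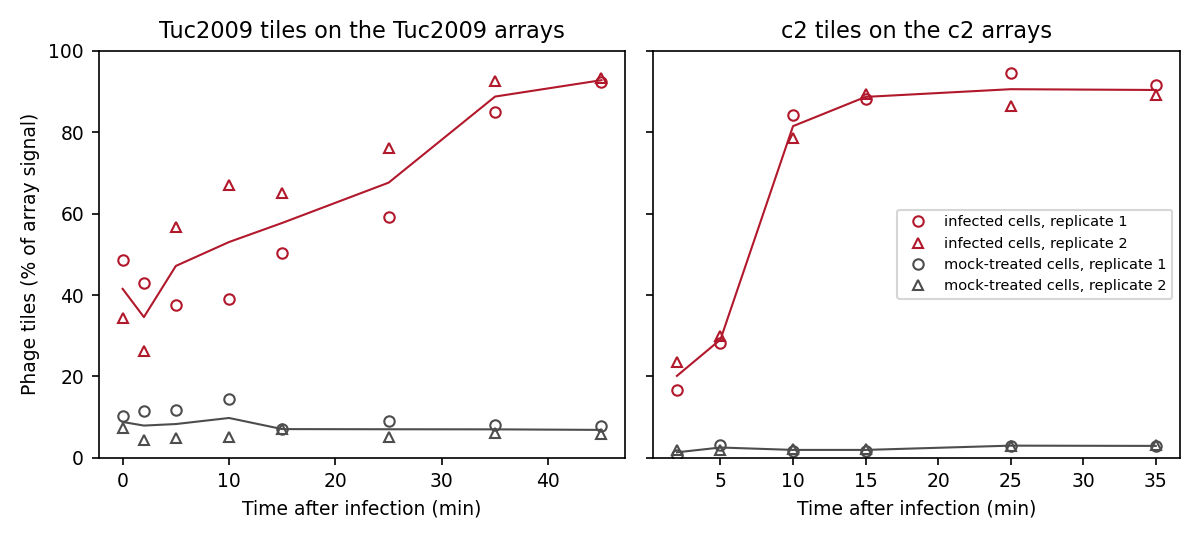
Share of the array signal (%) on tiles of the infecting phage against time after infection (min), with circles for replicate 1, triangles for replicate 2 and lines through the mean of both. The c2 share passed from 29.1% at 5 min to 81.5% at 10 min, while the Tuc2009 share climbed from 57.7% at 15 min to 92.8% at 45 min.

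Forward bins of Tuc2009 fell into 2 large blocks by the time from which they were called present. A bin of 1000 bp was called present from the time at which its forward or reverse ratio of infected over mock stayed more than 1 (log2) above its highest value on the c2 arrays. The bin at 3001 to 4000 was present from 0 min, positions 4001 to 9000 from 2 min and positions 9001 to 13000 from 5 min. At 0 min in replicate 1 reverse tiles were as bright, with forward minus reverse at -0.42 (log2) in the 2 bins from 3001 to 5000. Positions 13001 to 34000 were present from 25 min, together with 35001 to 38000, and the remaining bins from 35 min. The rule asks that a bin stay above the control, so these times are not those of the first signal. Between 22001 and 38000, forward tiles lay above reverse ones at 2 min by 3.59 (log2) in replicate 1 and 1.32 in replicate 2. At 15 min the excess was 0.48 and 0.21, and at 25 min it was 2.47 and 5.13. The bin at 4001 to 5000, which overlaps 2 predicted forward reading frames, rose from 0 min to the early window by 2.84 ± 0.79 (log2 of the infected level, SE, adjusted p = 0.024). The bin at 14001 to 15000 rose most between the early and late windows, by 4.83 ± 0.65 (SE, adjusted p = 6.24e-11), or 28.4-fold. Its late ratio of infected over mock was 7.53 ± 1.32 (log2, SD over 4 arrays). At most 19.4% of its mock tiles were above background on any of these arrays.

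Between consecutive windows, 4 forward Tuc2009 bins rose from 0 min to early, 5 from early to middle and 23 of 39 from middle to late. By limma 0 reverse bins rose between consecutive windows (0 at an unadjusted p under 0.05), and 36 of 39 fell from 0 min to early. The falls on both strands came to 0 without replicate 1, without replicate 2, with Agilent's processed signals and with the ratio in place of the level. The reverse bin at 1001 to 2000, which overlaps 2 predicted reverse frames, was present at 35 and 45 min. Without replicate 2, 5 bins rose from middle to late, 0 from 0 min to early and 0 from early to middle. The rises from 0 min to early and from early to middle came to 0 when the ratio of infected over mock was tested in place of the infected level. With the culture as a random block, 15 bins fell from middle to late where 7 did without it, and 38 fell from late to 45 min where 0 did by limma without it (34 at an unadjusted p under 0.05).

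For c2, the strands took mostly opposite ends of the genome. Reverse tiles at 1001 to 7000, which overlap 17 predicted reverse frames, and forward tiles at 7001 to 11000, which overlap 6 predicted forward frames, were present from 2 min by the same rule, with the Tuc2009 arrays as control. Forward tiles at 11001 to 19000 and at 20001 to 22000 followed at 10 min, and those at 3001 to 5000, inside the reverse region, were present at 35 min. From early to middle, 14 of 23 forward bins rose, and the bin at 13001 to 14000 rose most, by 4.26 ± 0.50 (log2, SE, adjusted p = 3.25e-14). From early to late it rose by 5.25 ± 0.50 (SE, adjusted p = 1.71e-20), or 38-fold. From middle to late, 7 forward bins rose and 5 reverse bins fell, and both with Agilent's processed signals and without replicate 2, 2 bins rose and 0 fell. The reverse bin at 3001 to 4000 had a ratio of 8.75 ± 0.09 (log2, SD, n = 2) at 10 min and 6.42 ± 1.34 at 35 min. On these arrays 11.3% to 24.8% of all c2 tiles were well above background in mock cells, so the size of such ratios depends on the background correction.

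**Figure D2:**
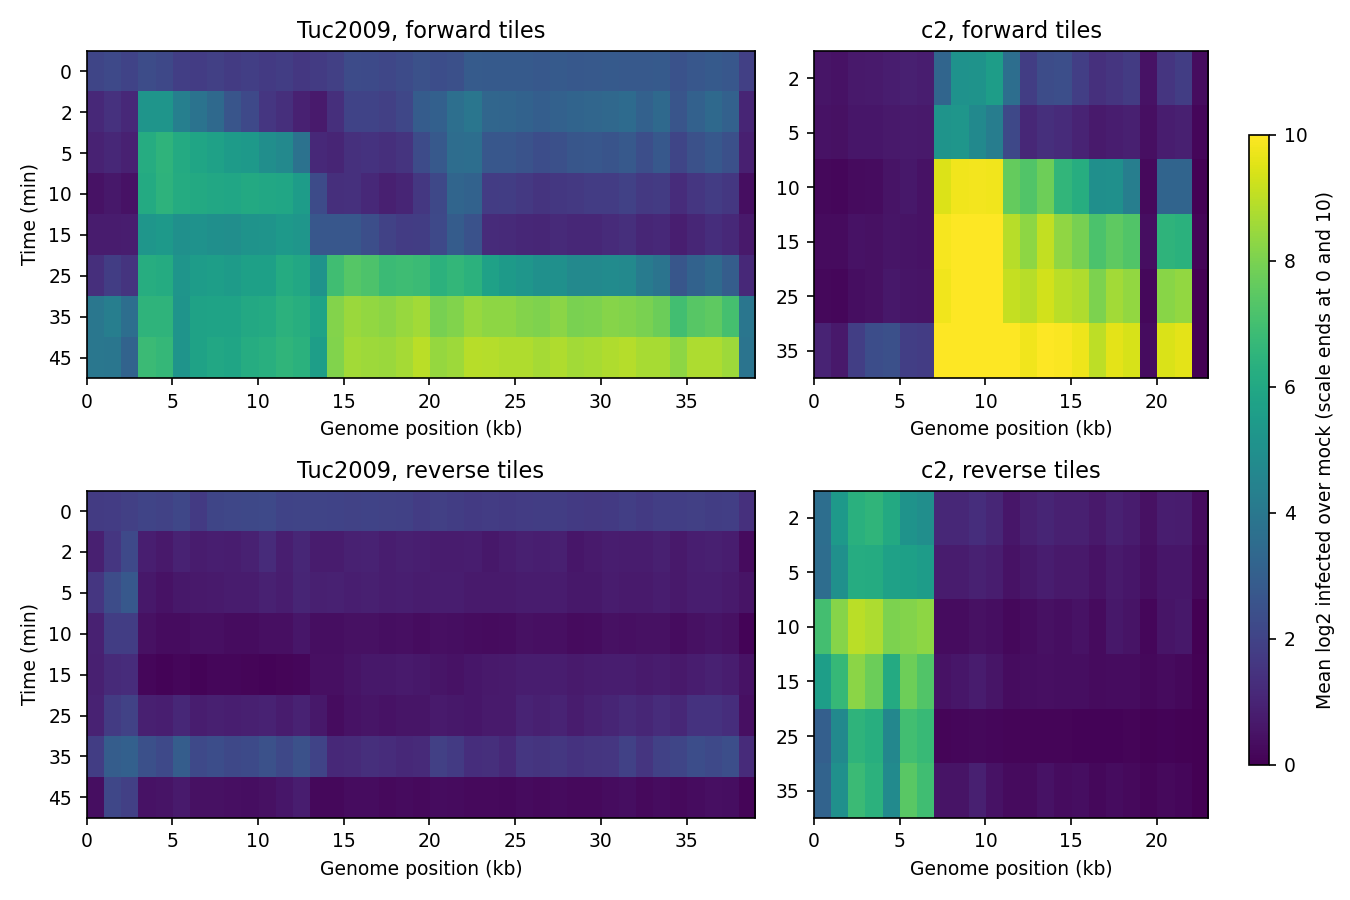
Mean log2 ratio of infected over mock (colour, 2 arrays per cell, values above 10 shown as 10) for bins of 1000 bp along each phage genome (kb) at each time (min), for forward and reverse tiles. Forward Tuc2009 bins between 13001 and 34000 were called present from 25 min, which does not exclude earlier signal. Reverse c2 bins between 1001 and 7000 are bright from 2 min.

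The forward late region of c2 held stretches with a low ratio. Forward tiles from 19325 to 20302 (175 tiles), inside a predicted frame of c2 from 19311 to 20456, had a late median of 0.17 (log2 infected over mock), against 8.84 for the tiles within 1000 bp on either side. Within this stretch 2.4% of tiles were well above background, and 90.5% were in the flanks. Shorter stretches lay at 11373 to 11559 (median 0.78, with 49% of tiles well above background), 18385 to 18557 (0.26, 1.1%) and 21965 to 22160 (-0.01, 13.4%). The bin at 19001 to 20000 stayed between 0.20 and 0.49 on average at all 6 times.

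**Figure D3:**
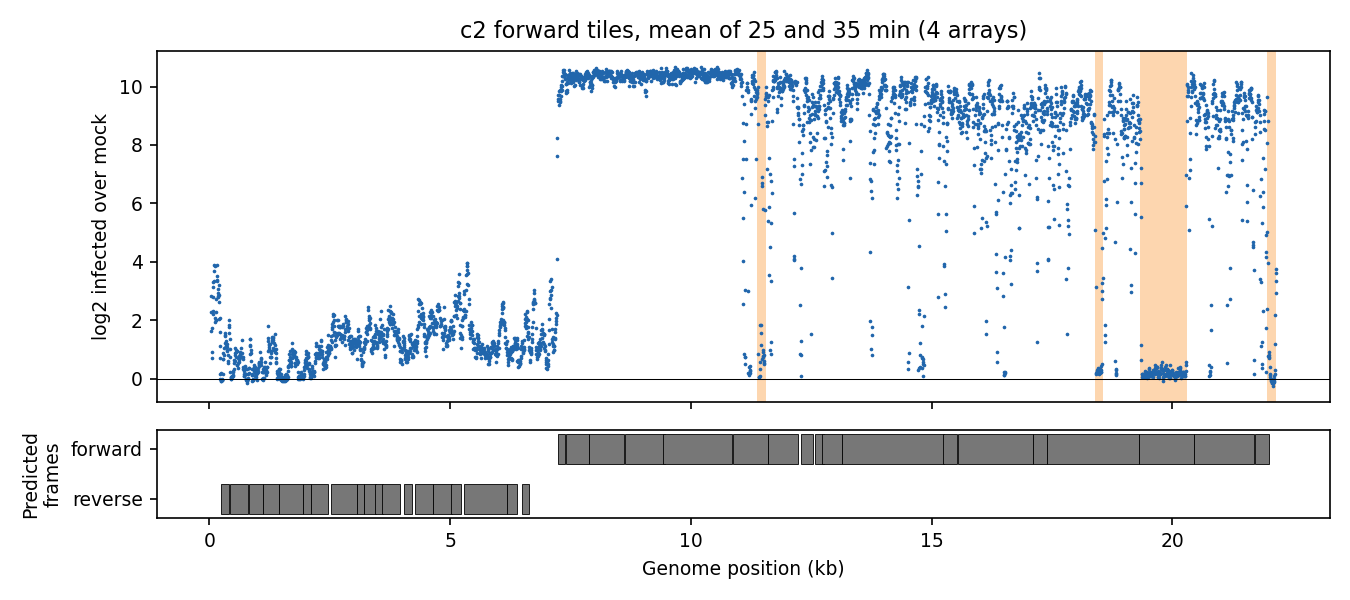
Log2 ratio of infected over mock for each forward c2 tile against genome position (kb), mean of 4 late arrays, with shaded stretches whose running median fell under 2 and predicted reading frames of both strands in the lower panel. The widest shaded stretch, from 19325 to 20302, had a median of 0.17 between flanks at 8.84.

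Late Tuc2009 infection changed 441 of 2580 host loci (limma, adjusted p under 0.05), 257 higher and 184 lower, with a median absolute change of 0.56 (log2). Among these, 53 changed at least 2-fold, 42 of them higher. The locus uc509_0279 rose by 2.83 ± 0.28 (log2, SE, n = 4, adjusted p = 2.49e-06), or 7.11-fold, after 1.51 ± 0.28 in the middle window. The highest value belonged to uc509_1922, at 4.74 ± 0.37 (adjusted p = 3.52e-07), whose 5 probes match the tiled Tuc2009 sequence between 11942 and 12290 with 90% to 100% identity. The locus uc509_1835 fell by 1.41 ± 0.23 (adjusted p = 0.000362) and uc509_0050 fell by 1.39 ± 0.15 (adjusted p = 4.82e-06). In the early window uc509_0050 was higher, by 1.03 ± 0.15 (adjusted p = 0.000421). At 0 min it was already higher, by 0.67 ± 0.21 (adjusted p = 0.0278), so the early value is not by itself a rise after infection. Without replicate 2, uc509_1835 did not pass (-1.17, adjusted p = 0.162), and with a loess on all probes uc509_0279 did not (0.23, adjusted p = 0.617).

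Loci with a predicted hydrophobic stretch, a feature of membrane proteins, were higher as a group in late Tuc2009 infection, with 31 risen and 4 fallen of 144 and a median of 0.17 (camera adjusted p = 0.000237). That call was lost with adjusted p = 0.803 with an estimated correlation, as were the following. The 39 tRNA loci had a median of 0.51, with 2 risen (adjusted p = 0.00236; adjusted p = 0.803 with an estimated correlation), and with the 0 min arrays subtracted their direction turned. The 98 loci of plasmid pCIS9 had a median of -0.16, with 11 fallen (adjusted p = 0.012; adjusted p = 0.803 with an estimated correlation), but per array it was -0.11 and 0.28 in replicate 1 and -0.48 and -0.37 in replicate 2.

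The Tuc2009 count was 663 at 0 min, 214 in the early window, 17 in the middle window and 140 at 45 min, with 105 of the last higher. Of the loci higher in the late window, 101 were also higher at 45 min, in arrays of the same cultures. Arrays with the same replicate number were taken as the same culture. Such Tuc2009 arrays deviated together in 25 of 28 pairs of times, meaning that differences between the replicates correlated across loci with r over 0.1. With the culture as a random block, the counts were 596 at 0 min, 111 early, 12 middle, 321 late and 141 at 45 min. Array quality weights or Agilent's processed signals took away nearly all of the 0 min count. Subtracting the 0 min arrays took away nearly all of the early count, with values given in the section on processing. The 0 min count was 9 without replicate 2 and 1026 without replicate 1, and without replicate 2 the middle count was 3, the late count 90 and the 45 min count 5. Without replicate 1 the early count was 93 and the middle count 97. Median centring without loess gave 195 late loci, of which 38.5% were higher in place of 58.3%, and a loess on all probes gave 2268, with 0.5% higher.

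Infection by c2 changed 177 host loci in the middle window, 111 higher and 66 lower, and 169 in the late window, 89 higher and 80 lower. In the early window 0 passed by limma, and 329 had an unadjusted p under 0.05. That count depended on the processing. Early loci passed with array quality weights, with median centring and without the lysogen and 0 min arrays. Few passed in a fit on the c2 arrays alone, with values given in the section on processing. The loci uc509_0687 and uc509_0685 rose late by 2.14 ± 0.16 (log2, SE, n = 4, adjusted p = 1.39e-07) and 2.06 ± 0.19 (adjusted p = 2.25e-06), or 4.40-fold and 4.18-fold. Both were also higher in late Tuc2009 infection, by 0.80 ± 0.16 (adjusted p = 0.00165) and 0.91 ± 0.19 (adjusted p = 0.0029). Late c2 minus late Tuc2009 passed for both, at 1.34 ± 0.22 (adjusted p = 0.000987) and 1.15 ± 0.27 (adjusted p = 0.0121). The loci uc509_2267 and uc509_2266 fell by 1.83 ± 0.32 (adjusted p = 0.00178) and by 1.32 ± 0.23 (adjusted p = 0.00196), and neither passed when replicate 1 or replicate 2 was left out (adjusted p = 0.0918 to 0.294), with values of -1.80 and -1.86 for uc509_2267 and of -1.47 and -1.17 for uc509_2266. The locus uc509_0279 was also higher in c2 infection, by 2.29 ± 0.28 (adjusted p = 9.73e-05) in the middle window and by 1.57 ± 0.28 (adjusted p = 0.0023) late. Between the middle and late windows, 46 higher and 34 lower loci were shared, in arrays of the same cultures.

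All 3 rRNA loci rose in late c2 infection, with a median of 1.53 (camera adjusted p = 0.000563; adjusted p = 0.0843 with an estimated correlation), and with median centring in place of loess their direction turned. The median of the rRNA loci per array ranged from 0.13 to 2.66. The 3 loci of plasmid pCIS1 had a median of 0.86, with 2 risen (adjusted p = 0.0145; adjusted p = 0.531 with an estimated correlation), but per array it was 1.57 and 1.45 in replicate 1 and 0.13 and 0.20 in replicate 2. Arrays of the same c2 culture deviated together in 9 of 15 pairs of times, and with the culture as a random block 98 loci passed in the middle window and 86 in the late window. The c2 counts rested on both cultures: they came to 1 and 13 in the middle window and to 6 and 59 in the late window when replicate 1 or replicate 2 was left out. Median centring gave 1455 and 1751, and Agilent's processed signals gave 388 and 648, with 41.0% and 41.4% higher in place of 62.7% and 52.7%.

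**Figure D4:**
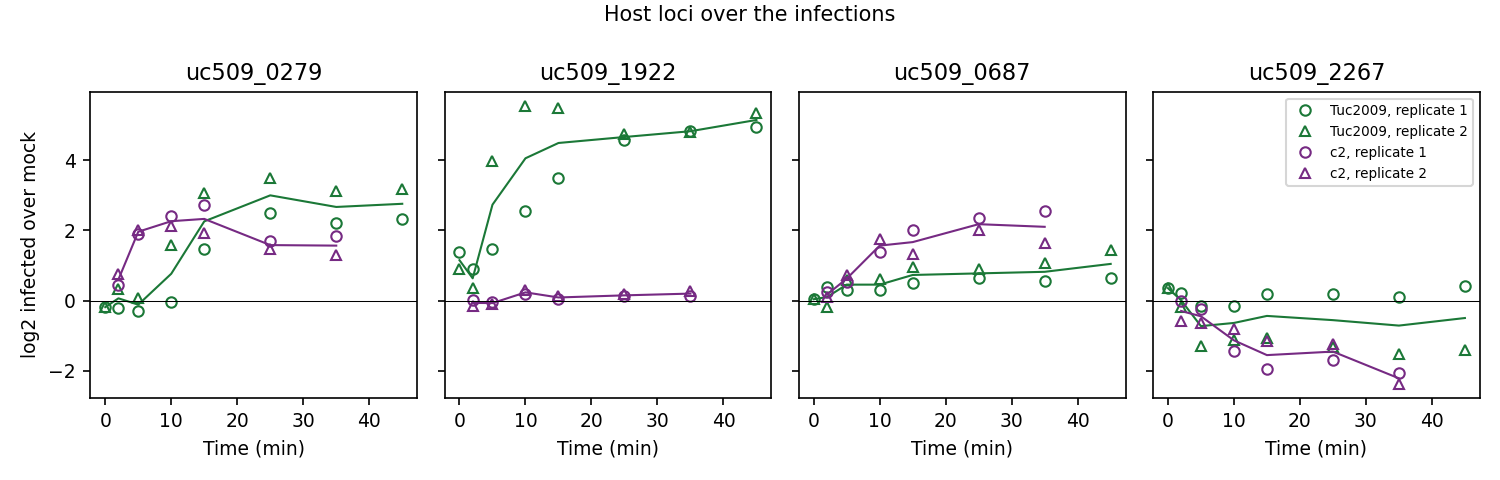
Log2 ratio of infected over mock against time (min) for 4 host loci, with circles for replicate 1, triangles for replicate 2 and lines through their mean. The locus uc509_0279 is higher late with both phages (2.83 and 1.57), and uc509_1922 with Tuc2009 (4.74).

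The phages were compared directly as the late c2 ratio minus the late Tuc2009 ratio, in which a dye effect that is constant for a locus cancels. In this contrast 177 loci differed, 42 higher and 135 lower with c2. The rRNA loci uc509_rRNA2 and uc509_rRNA3 were higher with c2, both by 2.47 ± 0.49 (log2, SE, n = 8, adjusted p = 0.00369 and 0.00353). The locus uc509_1506 was 7.66-fold lower with c2 (log2 -2.94 ± 0.31, adjusted p = 4.57e-05), after a late Tuc2009 rise of 2.57 ± 0.22. Its infected signal was not well above background on any of the 4 late c2 arrays, so the size of the difference is uncertain. The locus uc509_1922, with its match to Tuc2009, differed by -4.56 ± 0.52 (adjusted p = 4.57e-05), with infected signal above background on 6 of the 8 arrays. The difference for uc509_0279 was -1.26 ± 0.40 and did not pass (adjusted p = 0.0678).

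Loci that changed late with both phages were more numerous than independent lists would give, with 22 higher in both against 8.9 and 17 lower in both against 5.7 (Fisher's exact test, p = 3.27e-05 and p = 2.87e-05). A dye effect specific to a locus would also give shared directions, since infected RNA was green on every infection array. Fisher's test takes loci as independent, which adjacent tags were not, so its p-values are likely too small. The 39 tRNA loci lay lower with c2 (median -0.44, adjusted p = 0.00067; adjusted p = 0.761 with an estimated correlation) and the 98 pCIS9 loci lay higher (median 0.26, adjusted p = 0.00067; adjusted p = 0.808 with an estimated correlation). The tRNA median per late array was between -0.39 and 0.37 with c2 and between 0.08 and 0.76 with Tuc2009. For pCIS9 it was between 0.00 and 0.11 with c2, so that difference rests on Tuc2009 replicate 2. No slide or scan day held arrays of both infections, so phage and slide cannot be told apart, and with the culture as a random block 121 loci differed. The count was 10 without c2 replicate 1, 63 without c2 replicate 2, 59 without Tuc2009 replicate 2 and 213 without Tuc2009 replicate 1, and with a loess on all probes it was 1891, with 95.1% higher and both rRNA loci reversed. The rRNA loci also did not pass with median centring (1.43 and 1.44), without c2 replicate 1 (2.48 and 2.58) or without Tuc2009 replicate 2 (2.37 and 2.42), and uc509_1506 did not with the loess on all probes (-0.54).

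The lysogen was compared with the cured strain to see whether the resident prophage alters host transcripts, and the labels give no growth stage for these arrays. In the lysogen 1129 host loci differed, 559 higher and 570 lower, and 336 of them at least 2-fold. The adjacent tags uc509_0140 and uc509_0141 were higher by 3.49 ± 0.50 (log2, SE, n = 2, adjusted p = 6.65e-05) and 3.02 ± 0.40 (adjusted p = 3.03e-05), or 11.2-fold and 8.13-fold. On the single arrays they were at 2.54 and 4.44, and at 2.23 and 3.81. The fit assumes the same spread in all 15 groups. Host ratios of the lysogen arrays had an SD of 1.05 and 0.89 (log2), within a range of 0.19 to 1.05 over all arrays. These SE, p-values and the count may therefore understate the spread between lysogen arrays. The locus uc509_tRNA27, which has 1 probe, fell by 4.70 ± 0.56 (adjusted p = 9.76e-06). The locus pCIS4_009 was lower by 4.62 ± 0.73 (adjusted p = 0.000151), at -5.31 and -3.92 on the single arrays. Its lysogen signal was not above background on either array, so the size of the difference is uncertain.

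Of 39 tRNA loci, 34 fell in the lysogen, with a median of -3.12 (camera adjusted p = 5.08e-20; adjusted p = 0.283 with an estimated correlation). Their median was -3.43 and -2.74 on the single arrays, and between 0.00 and 2.25 on the Tuc2009 arrays. Of 9 loci of plasmid pCIS4, 6 fell, with a median of -2.70 (adjusted p = 0.00533; adjusted p = 0.92 with an estimated correlation). Among 151 loci that share a probe sequence with at least 2 others, 83 fell (adjusted p = 1.15e-05; adjusted p = 0.92 with an estimated correlation), but their median was -1.89 on one array and 0.11 on the other. The ratios of both lysogen arrays correlated across loci with r = 0.30. Of the 1129 loci, 1047 had the same direction on both, which choosing them on the mean of these arrays favours. With array quality weights 36 loci passed, without uc509_0140, uc509_tRNA27 and pCIS4_009 (3.49, -4.70 and -4.62, adjusted p = 0.0598, 0.0743 and 0.197), and 717 passed without replicate 1. A loess on all probes gave 62, with 9.7% higher, and with median centring 611 passed, of which 80.7% were higher in place of 49.5%.

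Prophage bins were called raised in the lysogen by a ratio over the cured strain more than 1 (log2) above the highest c2 bin on both arrays, and 11 of 78 Tuc2009 bins were raised, 9 forward and 2 reverse. The reverse bin at 2001 to 3000, which overlaps 1 predicted reverse frame from 2046 to 2906, was at 2.59 ± 0.15 (log2, SD, n = 2) and that at 1001 to 2000 at 1.99 ± 0.03. The highest forward bin was at 21001 to 22000, at 2.80 ± 0.15, inside a raised stretch from 19001 to 24000. Other raised forward bins lay between 28001 and 36000, at 1.29 ± 0.25 to 1.40 ± 0.41. Every forward bin from 3001 to 38000 lay above the highest c2 bin of each array (0.04 and 0.45). Most of them did not exceed it by more than 1 (log2) on both arrays, so the raised bins do not mark the limits of the signal. The c2 tiles, the control for hybridisation without target, had bin medians of -0.345 and 0.40. With Agilent's processed signals the means over the raised bins were 4.48 forward and 4.67 reverse, in place of 1.75 and 2.29. In the cured strain 6.2% and 3.8% of Tuc2009 tiles were well above background, so the size of these ratios depends on the background correction.

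**Figure D5:**
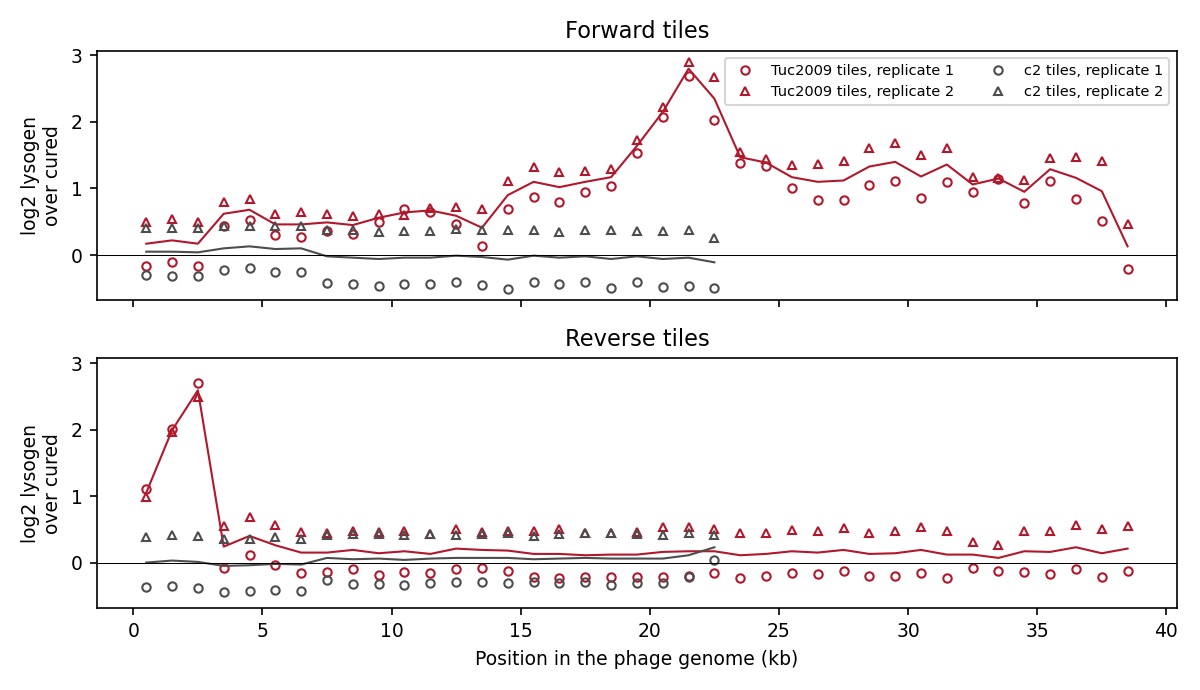
Log2 ratio of lysogen over cured strain for bins of 1000 bp against position in the phage genome (kb), with red for Tuc2009 tiles, grey for c2 tiles, circles and triangles for both replicates and lines through their mean. Reverse bins between 1001 and 3000 and forward bins between 19001 and 24000 stand more than 1 (log2) above the highest c2 bin on both arrays. Forward bins from 3001 to 38000 all lie above it, most by a smaller margin.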

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

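The test of the difference and the count of other splits of the late arrays were planned, and the count of splits that keep cultures whole was chosen after the result was seen. The loci named here differed between the infections by the test of the difference itself, the late c2 ratio minus the late Tuc2009 ratio. That test picked out 177 loci. The values were 2.47 for uc509_rRNA2 and 2.47 for uc509_rRNA3, higher with c2, and -4.56 for uc509_1922 (infected signal above background on 6 of the 8 arrays) and -2.94 for uc509_1506 (on 4 of the 8 and on none of the c2 arrays, so its size is uncertain), lower with c2. The 8 late arrays can be divided into groups of 4 in 35 ways. In a fit with the late arrays in 2 groups the real split gave 218 loci and the highest of the others gave 1. Arrays of the same culture deviated together (r over 0.1) in 25 of 28 pairs of times for Tuc2009 and in 9 of 15 for c2. Each Tuc2009 culture lay on its own slides and scan day, so culture and slide cannot be told apart there. Of the splits, 3 keep the cultures whole, which is too few for a share under 0.05. With 2 cultures per phage and no shared slide, the splits do not separate the phage from the culture or slide.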

How the results depend on the processing

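The settings without the lysogen and 0 min arrays, without loci matching the phages and with both channels above background, the classes, for bins the ratio in place of the level and the culture block, and for lysogen bins leaving out replicates, were chosen after seeing the data, and the other tests before. Of 336 alternative values of counts and levels, 205 stayed within 1.5 times the reported count or within the spread between replicates, and 131 moved. Of 306 alternative values for the named loci, 288 kept direction and threshold, 16 lost the threshold and 2 reversed. Of 88 for classes, 37 kept both, 48 lost the threshold and 3 reversed. Except where the construction shows it (fewer arrays, a fold minimum), the cause was not tested. Counts below are host loci unless stated, in the order given. The dim infected channel of late c2 arrays, with 48.5% of loci above background at the lowest, limits what those arrays can show.

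With replicates left out, a lone array is assumed to vary like the other groups, and for bins the times of a window stand in for replicates. Tuc2009 counts then ranged from 9 to 1026 at 0 min, 93 to 200 early, 3 to 97 middle, 90 to 392 late and 5 to 138 at 45 min. For c2 they ranged from 1 to 13 middle and 6 to 59 late, for the difference from 10 to 213 and for the lysogen from 717 to 1092. The share of Tuc2009 bins rising ranged from 0 to 5.1% from 0 min to early, 0 to 6.4% from early to middle and 6.4% to 30.8% from middle to late. The share falling was 0 from 0 min to early and ranged from 0 to 12.8% from middle to late. For c2 from middle to late, 4.3% to 10.9% rose and 0 to 10.9% fell. Late forward medians ranged from 5.69 to 7.31 for Tuc2009 and from 8.18 to 8.55 for c2, late reverse medians from 1.21 to 1.45 and from 0.31 to 0.34, and lysogen bins from 1.57 to 1.94 forward and 2.22 to 2.36 reverse.

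The 0 min arrays of Tuc2009 were subtracted for both phages, since c2 has none of its own. With this, 1 locus passed early and 1 middle for Tuc2009, and 352 early, 388 middle and 73 late for c2. Class calls late in Tuc2009 infection came to 2, and the tRNA class reversed (adjusted p = 0.00615 by camera in limma). With Agilent's processed signals the counts were 2 at 0 min, 43 early, 27 middle and 72 at 45 min for Tuc2009, 388 middle and 648 late for c2, and 327 for the difference. The share of Tuc2009 bins rising was 0 from 0 min to early and 2.6% from early to middle, and the share falling was 0 from 0 min to early, 0 from middle to late and 30.8% from late to 45 min. For c2 4.3% rose and 0 fell from middle to late. Late medians were 9.72 forward and 3.65 reverse for Tuc2009 and 11.76 forward for c2, and lysogen bins were at 4.48 forward and 4.67 reverse. The deposited series values gave 165 at 0 min, 50 early, 27 middle and 64 at 45 min, then 387 middle and 801 late for c2 (19.7% higher in place of 52.7%), and 415 for the difference.

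Array quality weights gave 0, 749, 414, 791 and 375 for Tuc2009 from 0 to 45 min, 81, 648 and 440 for c2, 395 for the difference and 36 for the lysogen. At least 2-fold, the counts were 77, 19, 8, 53 and 45, then 21 middle and 34 late for c2, 74 for the difference and 336 for the lysogen. Detection on all 30 arrays gave 357 at 0 min and 9 middle for Tuc2009.

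Median centring gave 45 early, 5 middle, 195 late and 16 at 45 min for Tuc2009, 72, 1455 and 1751 for c2, 333 for the difference and 611 for the lysogen (80.7% higher in place of 49.5%). Class calls in the difference came to 4, and the rRNA class late in c2 infection (adjusted p = 0.905 by camera in limma) and the class sharing probe sequences in the difference (adjusted p = 0.163) reversed. It moved the median of all loci by -0.17 to 0.31 (log2) over the arrays. A loess on all probes moved it by -2.19 to -0.05 and gave 518 early, 1 middle, 2268 late and 996 at 45 min for Tuc2009 (0.5% higher late in place of 58.3%), 306 middle for c2, 1891 for the difference (95.1% higher in place of 23.7%) and 62 for the lysogen (9.7% higher). The difference of uc509_rRNA2 reversed to -1.73 and that of uc509_rRNA3 to -1.87.

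With the culture as a random replicate block the counts were 111 early for Tuc2009, and 98 middle and 86 late for c2. For bins this block gave 19.2% falling from middle to late, and 5.1% rising and 48.7% falling from late to 45 min. As a fixed block it gave 322 early, 93 middle and 228 at 45 min for Tuc2009, 2 early and 272 middle for c2, and 276 for the difference. Fits on the arrays of a single phage gave 329 early and 111 middle for Tuc2009, and 2 early and 388 middle for c2. Without the lysogen and 0 min arrays the counts were 721, 193, 827 and 289 for Tuc2009 from early to 45 min, 160, 511 and 385 for c2, and 348 for the difference.

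With an estimated correlation in camera 0 class calls held in the 4 comparisons (unadjusted p under 0.05: 0 late with Tuc2009, 1 late with c2, 2 in the difference, 1 in the lysogen), and fry gave 2 late in Tuc2009 infection and 3 in the difference. With the ratio of infected over mock in place of the level, the share of Tuc2009 bins rising was 0 from 0 min to early, 0 from early to middle and 3.8% from late to 45 min, and the share falling was 0 from 0 min to early and 0 from middle to late. The mean over tiles gave late c2 medians of 5.97 forward and 1.89 reverse, and unsaturated tiles gave 7.58 forward.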

Other observations

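The tests in this part were chosen after the result was seen, except the 0 min counts with a replicate left out, which were planned.

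Host loci that passed lay next to each other along the chromosome tags. In late Tuc2009 infection 137 pairs of adjacent tags changed in the same direction, where 1000 shuffles gave a mean of 38.7 and at most 58 (permutation p = 0.001, the smallest they can give). A candidate explanation is that neighbours are read from shared transcripts, for which the data hold no further test. In late c2 infection there were 53 such pairs against a mean of 5.1, and in the lysogen 443 against 221.5. The longest run held 7 loci with Tuc2009, 8 with c2 and 14 in the lysogen.

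The 9 loci of plasmid pCIS4 had different values in both Tuc2009 cultures. In replicate 2 their median went from 0.74 at 0 min to 2.16 at 45 min, while in replicate 1 it lay between -0.37 and 0.71. In the c2 series it lay between -0.01 and 0.81. Loci sharing a probe sequence with at least 2 others had a median between -1.41 and 0.19 over the c2 arrays and between -0.41 and 0.07 over the Tuc2009 arrays.

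The second Tuc2009 block brightened in the order of its positions. From 25 to 35 min the change of the 24 forward bins from 14001 to 38000 grew with position in both replicates, with Spearman's rho of 0.91 and 0.99 across bins, which are not independent replicates (permutation p = 1e-05, the smallest given; adjusted p = 2e-05 over 8 relations). Transcription proceeding from the upstream end may account for it. From 15 to 25 min the largest change lay upstream in replicate 1 (rho = -0.98), and in replicate 2 rho was -0.26. Transcription from the upstream end would also give a larger upstream change in the earlier interval. In the upstream block (3001 to 13000), rho from 2 to 5 min was 0.12 and 0.99, and for forward c2 bins from 10 to 15 min it was 0.79 and 0.41.

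The locus uc509_1922 may report phage transcripts. In Tuc2009 replicate 2 its ratio went up by 5.18 (log2) from 2 to 10 min and that of the 73 forward tiles it matches by 6.08, a difference of -0.90. A change of the host transcript itself was not separated from this.

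Tuc2009 tiles of both strands were bright at 0 min in replicate 1, with a median of 3.35 forward and 2.85 reverse. A second cDNA strand copied as a fixed share of forward signal would make reverse tiles follow forward ones, but the reverse median of bins was higher at 0 min than at 45 min by 2.52 and than at 35 min by 0.71, so it stays open with a share that varies between arrays. Transcription of the upstream block alone would raise forward tiles above reverse ones, and in its 2 upstream bins they differed by -0.42. Phage DNA in the labelled sample would raise both strands alike and stays open for that block (forward minus reverse -0.94, reverse ratio 3.31), but not alone for positions 22001 to 38000, where forward tiles lay above reverse ones at 2 min by 1.32 and 3.59. RNA carried over with the phage stock also stays open downstream, where the forward excess changed from 2 to 15 min by -1.10 in one replicate and -3.11 in the other, but went from 0 to 2 min from 0.37 to 1.32 and from 1.71 to 3.59, which goes against it.

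Poor hybridisation of its probes stays open for the stretch of c2 from 19325 to 20302, which had a low late ratio: it differed from its flanks by -0.23 where c2 tiles were raised without c2, but this is the array of Tuc2009 0 min replicate 2 alone. In c2 replicate 1 at 2 min, reverse tiles of the stretch also lay below their flanks, by -0.64, at 0.82 beside 0.79 for Tuc2009 tiles, a difference of 0.03. In replicate 2 the flanks themselves were at 0.14, too low for this comparison. A phage stock whose sequence differs there and a stretch that is present but not transcribed cannot be told apart, because 1 array bears on it and the nucleic acid behind the reverse signal is not known. No biological explanation was tested beyond this.

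The 663 host loci at 0 min rest largely on the array of replicate 2, since 9 passed without it and 1026 without replicate 1. On the 0 min array of replicate 2, c2 tiles carried 15.5% of the infected signal without c2. Its host ratios had an SD of 0.85 (log2), beside 0.33 in replicate 1. A dye effect fixed for each locus would be seen again on other arrays. The 663 loci had a median of 0.08 (quartiles 0.03 and 0.15) in their 0 min direction over the other 26 infection arrays, beside 0.67 (0.54 and 0.84) at 0 min. They were chosen for large values at 0 min, so part of this fall was fixed in advance. How much it weighs against a dye effect is therefore not known, and both quartiles kept the 0 min direction. A response shared by both cultures stays open. At 0 min r across loci between the replicates was 0.23, beside 0.45 to 0.65 at the later Tuc2009 times and -0.09 to 0.67 in the c2 series. Of the 663 loci, 600 had the same direction in both replicates. They were chosen on the mean of these same arrays, which favours that, so this count does not bear on a shared response.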
